A study of Homo sapiens with 12 samples.

How the data were processed

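RNA-seq of MDA-MB231 cells with stable hairpins (sh_control, sh_TDP43, sh_SRSF3) and RIP-seq with matched inputs for Flag-TDP43 and Flag-SRSF3 were used. Groups and replicate numbers were taken from the sample titles. The labels also name a combined knockdown of TDP43 and SRSF3. Per-sample columns of the count table whose names match no label numbered 2, and these columns were not used, so the combined knockdown and the interaction were not analysed here. The fits therefore held 6 libraries with 3 residual degrees of freedom, where 8 libraries and 4 degrees of freedom had been planned. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Only 1 hairpin per target is named in the labels.

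Per the file headers, the deposited values for the knockdowns are raw read counts per gene from featureCounts v1.4.6-p5, counted over exons with no strand option and no option for read pairs, on an annotation of protein-coding and lincRNA genes. STAR 2.5.2a, HISAT2 2.0.5, StringTie 1.3.0, Cufflinks and GRCh37 are named in the submitters' processing notes, without saying which was used for which file. Coordinates in the count table are those of GRCh37. Without strand, reads of a gene and an antisense or overlapping gene cannot be told apart, and reads matching several copies of a gene family were left out of the counts. Per the file headers, the deposited RIP table holds FPKM per gene, that is reads or fragments scaled by gene length and library depth. Its coordinates match GRCh38, so none of them is printed beside those of the count table. The same table holds the authors' log2 fold changes of RIP over input; it holds none for the knockdowns, so deposited fold changes were compared for the RIPs alone. A second deposited table gives a normalised signal per gene for the same RIP and input libraries; its unit is not given in the sources used here, and it served as an alternative chosen after seeing the data. The tool behind each RIP table is not given in the sources used here.

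The count table has 27745 genes. Names came from the files for 27068 of them and from a reference table of gene names for 89, and 588 stayed unnamed. The RIP table has 60675 genes. Counted reads per library were 37486911 and 37987194 in sh_control, 34992427 and 34457445 in sh_TDP43, and 35912547 and 38326930 in sh_SRSF3. Libraries of a group differed by more than sampling noise (chi-square per gene 23.6 in sh_control, 12.7 in sh_TDP43 and 11.3 in sh_SRSF3), so none was counted as a repeat. Depth of the RIP libraries was inferred from the lowest step of FPKM times gene length, as 27.7 M reads for both RIPs, 28.4 M for the TDP43 input and 28.2 M for the SRSF3 input.

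Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F-test, which is two-sided), all 6 libraries in one fit without covariates, leaving 15026 genes. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM with their SD over 2 libraries. The procedure was tested on simulated counts with 14526 genes tested. Every gene had the same dispersion (spread between libraries, 0.00959), and 200 genes were changed per knockdown. In the data the spread differs between genes and far more genes were called, so these rates need not hold there. In the simulation of sh_TDP43 against sh_control, 58.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97% of those changed 4-fold were called, with 5 unchanged genes called. In that of sh_SRSF3 these were 46.3%, 89.6% and 90.9%, with 6 unchanged genes called.

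Before the data were examined, 28 gene lists, the comparisons, the tests and the rule for named genes were fixed. The lists cover SR proteins, hnRNP proteins, known TDP43 splice targets, cell polarity, Notch, epithelial, mesenchymal, invasion, TGF-beta and YAP, G2/M, DNA replication, p53, apoptosis, interferon, NF-kB, unfolded protein response and ATF4, hypoxia and glycolysis, cholesterol synthesis, histones, cytosolic ribosomal proteins, oxidative phosphorylation, long noncoding RNAs, mitochondrially encoded genes, immediate early genes and markers of luminal breast, fibroblast, haematopoietic and embryonic kidney packaging cells. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and adjusted over the lists of each comparison. With an estimated correlation 0 of 28 lists passed in each of the 3 comparisons, so no list call holds under it. That variant rests on the 3 residual degrees of freedom of the fit and had little power. In sh_SRSF3 the haematopoietic list had an estimated correlation of 0.006, below the preset one, yet its camera adjusted p went from 0.0297 to 0.61. Failing under this variant therefore does not show that a list call is false. The fry test asks whether a list's genes move one way and does not compare them with other genes.

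Named genes are TARDBP, SRSF3, PARD3 and NUMB, then for each knockdown the 8 rising and 8 falling genes with the largest log2 change among called genes with a mean log2 CPM above 2, both knockdown libraries beyond both controls and a symbol that is not a clone name, and 4 each way between the knockdowns. Up to 4 members with the lowest adjusted p per list could be named, and members that moved against a list are among these. The mean runs over 6 libraries, where 8 had been planned. In each RIP they are the 10 highest and 5 lowest ratios among genes with a mean of at least 10 FPKM. MALAT1, NEAT1 and GAPDH in the RIPs were chosen besides.

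RIP ratios are log2((RIP + 1)/(input + 1)) of FPKM for genes at 1 or more in either library, and at least 2-fold counts as enriched. Such ratios understate the change of low genes. Medians of lists and families were also taken relative to all genes in the same of 10 bins of expression level, a step chosen after seeing the data. List medians in the RIPs were set against 10000 random lists matched on expression. They were taken from the FPKM table alone. Overlap of calls was set beside independent lists and beside 40 simulations in which every library, controls included, was drawn around the control level. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, other filters, the groups of a comparison alone, the replicate number as a block, leaving out each replicate in turn, other pseudocounts and thresholds for the RIPs, and fry or an estimated correlation for lists. Where leaving out a library left a group with 1 library, that library was assumed to vary like the other groups.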

Results

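RNA was measured in MDA-MB231, an established triple-negative breast cancer cell line, after stable lentiviral expression of a short hairpin RNA against TDP43, a short hairpin RNA against SRSF3 or a control hairpin. TDP43, encoded by TARDBP, is a nuclear RNA-binding protein that represses cryptic exons, and SRSF3 is a serine- and arginine-rich splicing factor. Each of these 3 groups had 2 RNA-seq libraries, with 34457445 to 38326930 counted reads per library. RNA immunoprecipitation (RIP), in which RNA bound to a tagged protein is pulled down with an antibody, was measured for Flag-tagged TDP43 and Flag-tagged SRSF3, with 1 RIP library and 1 input library each.

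TARDBP (ENSG00000120948; GRCh37 chromosome 1, 11072401 to 11086477) was at 146 ± 31 CPM (TMM-scaled counts per 1e6 counted reads; SD, n = 2) in the control libraries and at 32.9 ± 2.2 (SD, n = 2) in the sh_TDP43 libraries. Its level fell by 2.15 on the log2 scale (SE 0.13, edgeR quasi-likelihood adjusted p = 3.51e-08). SRSF3 (ENSG00000112081; chromosome 6, 36562130 to 36573377) was at 431 ± 39 in the control libraries and at 62.9 ± 1.6 (both SD, n = 2) in the sh_SRSF3 libraries. It fell by 2.78 on the log2 scale (SE 0.10, adjusted p = 1.63e-10). Each target therefore changed as its library label says. Each knockdown also had less of the other gene's RNA. SRSF3 was at 184 ± 5 CPM (SD, n = 2) in sh_TDP43, a log2 change of -1.23 (SE 0.10, adjusted p = 3.05e-07). TARDBP was at 105 ± 4.5 (SD, n = 2) in sh_SRSF3, a log2 change of -0.48 (SE 0.12, adjusted p = 0.00326). Without control replicate 1 the latter change was -0.25, with an adjusted p of 0.0571.

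**Figure D1:**
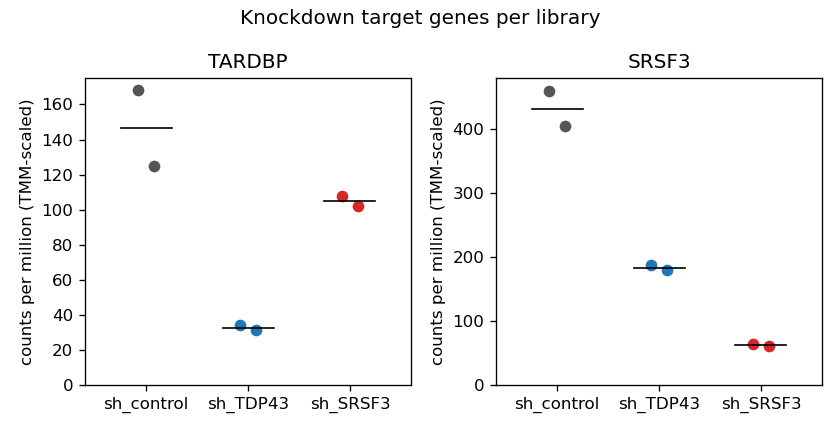
CPM, TMM-scaled, of TARDBP (left) and SRSF3 (right) in each library (points) of the 3 groups, with group means (lines). Means of TARDBP are 146, 32.9 and 105 in sh_control, sh_TDP43 and sh_SRSF3, and those of SRSF3 are 431, 184 and 62.9.

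PARD3 and NUMB, which act in cell polarity and asymmetric division, were examined in every comparison. PARD3 (chromosome 10, 34398488 to 35104253) rose in both knockdowns, by 0.46 on the log2 scale in sh_TDP43 (SE 0.10, adjusted p = 0.00137) and by 0.76 in sh_SRSF3 (SE 0.10, adjusted p = 8.2e-06). NUMB (chromosome 14, 73741815 to 73930348) rose in sh_TDP43 rose by 0.41 (SE 0.10, adjusted p = 0.00572), a call that ended without control replicate 1 (adjusted p = 0.0594) or sh_TDP43 replicate 2 (adjusted p = 0.0729). In sh_SRSF3 the log2 difference of NUMB was 0.23 (SE 0.10), with an adjusted p of 0.066, which became 0.00918 without control replicate 2.

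The comparison of sh_TDP43 with sh_control asks which RNAs change when TDP43 is depleted. Genes of DNA replication, hypoxia and glycolysis, and invasion proteases and integrins were lower as lists after TDP43 knockdown at the preset correlation. None of these calls held with an estimated correlation (camera adjusted p = 0.64 each). The nuclear RNA NEAT1, the scaffold of paraspeckles, was higher. NEAT1 went from 411 ± 42 to 3350 ± 240 CPM (SD, n = 2), a log2 rise of 3.03 (SE 0.11, adjusted p = 1.53e-09). MALAT1, another abundant nuclear RNA, rose by 1.01 (SE 0.14, adjusted p = 6.81e-05). PFKP, a phosphofructokinase gene whose transcript is a known target of TDP43 in splicing, fell from 534 ± 62 to 107 ± 21 CPM (SD, n = 2), a log2 change of -2.32 (SE 0.13, adjusted p = 2.38e-08).

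Of 15026 genes tested, 6728 passed an adjusted p of 0.05, with 3105 higher and 3623 lower in sh_TDP43, and 1906 of these changed at least 2-fold (939 higher, 967 lower). Upper-quartile scaling in place of TMM shifted the median of all genes by 0.09 and gave 3956 higher and 2978 lower. The strongest rises among genes with an adequate mean level were those of the receptor phosphatase genes PTPRQ (log2 change 5.73, SE 0.32; chromosome 12, 80799774 to 81072802) and PTPRR (3.63, SE 0.24). They were followed by the noncoding RNAs LINC01204 (3.53) and LINC00886 (3.47), the GDNF family receptor gene GFRA1 (3.25), the alkaline phosphatase gene ALPP (3.25), NLRP10 (3.21) and the peptidylarginine deiminase gene PADI1 (3.17). PTPRQ was at 0.251 ± 0.051 CPM in the controls and at 13.5 ± 1.7 in sh_TDP43 (SD, n = 2). At an adequate mean level, the strongest fall was that of the organic anion transporter gene SLCO4A1 (-4.45, SE 0.16, chromosome 20, 61273797 to 61317137). Next came the hyaluronan-degradation gene CEMIP (-3.97), the replication gene GINS2 (-3.93), MARCKSL1 (-3.76) and ZNF488 (-3.52). After these were the cell cycle transcription factor gene MYBL2 (-3.26), the NADPH oxidase gene NOX5 (-3.18) and the cytokine gene IL11 (-3.11). Adjusted p-values of these 16 genes lay between 1.53e-09 and 8.6e-07. ALPP has near-identical paralogs, so its count is uncertain.

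The DNA replication list had 23 of its 28 tested members lower and 0 higher, over all genes and also adjusted over the list alone, with a median log2 change of -0.64 (camera adjusted p = 3.14e-06; adjusted p = 0.64 with an estimated correlation). CDC6, a licensing factor gene, fell by 1.35 (SE 0.11), and RRM2, a ribonucleotide reductase gene, fell by 1.78 (SE 0.16). In the hypoxia and glycolysis list, 19 of 30 members fell and 2 rose, the same numbers adjusted over the list alone (median -0.44, adjusted p = 0.00104; adjusted p = 0.64 with an estimated correlation). NDRG1 fell by 2.52 (SE 0.13), the glucose transporter gene SLC2A3 fell by 1.70 (SE 0.11) and PFKFB3 fell by 1.61 (SE 0.11). Invasion protease and integrin genes fell in 15 of 21 cases and rose in 2, with identical numbers adjusted over the list alone (median -0.63, adjusted p = 0.00331; adjusted p = 0.64 with an estimated correlation). PLAU, which encodes urokinase, fell from 534 ± 57 to 80.5 ± 7.6 CPM (SD, n = 2), a log2 change of -2.73 (SE 0.11, adjusted p = 2.09e-09). The integrin genes ITGA6 and ITGB1 changed by -1.97 (SE 0.10) and -1.12 (SE 0.10), and the membrane protease gene MMP14 by -1.31 (SE 0.11).

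Among genes for hnRNP proteins, which package nascent RNA, 19 of 30 fell and 1 rose, as they did adjusted over the list alone (median -0.32, adjusted p = 0.00133; adjusted p = 0.64 with an estimated correlation). The list contains TARDBP. PTBP1 changed by -1.29 (SE 0.12) and HNRNPDL by -0.98 (SE 0.09), while HNRNPH2 rose by 0.65 (SE 0.09). Apoptosis regulators fell in 10 of 18 cases and rose in 1, with identical numbers adjusted over the list alone (median -0.46, adjusted p = 0.00602; adjusted p = 0.64 with an estimated correlation). Members on both sides of the pathway were lower. The anti-apoptotic gene BCL2L1 fell by 1.57 (SE 0.10) and among pro-apoptotic genes APAF1 fell by 1.42 (SE 0.11), BCL2L11 fell by 1.28 (SE 0.15) and BAK1 fell by 0.86 (SE 0.10). Immediate early genes fell in 12 of 19 cases and rose in 1, also when adjusted over the list alone (median -0.64, adjusted p = 0.0242; adjusted p = 0.64 with an estimated correlation), with FOSL1 at -1.24 (SE 0.10) and NR4A1 at -1.54 (SE 0.19). Notch pathway genes fell in 11 of 18 cases and rose in 2, again with the same numbers adjusted over the list alone (median -0.46, adjusted p = 0.0298; adjusted p = 0.64 with an estimated correlation). The ligand gene JAG1 fell by 1.52 (SE 0.13) and LFNG, a glycosyltransferase gene that modifies Notch, fell by 1.87 (SE 0.19). Without control replicate 2 the adjusted p was 0.0626 for the immediate early list and 0.0675 for the Notch list.
Genes for SR proteins, the splicing factor class of SRSF3, fell in 9 of 13 cases; adjusted over the list alone 9 fell and 1 rose (median -0.26, adjusted p = 0.0402; adjusted p = 0.64 with an estimated correlation). This list contains SRSF3, and its other strong members were SRSF2 (-0.69, SE 0.11) and TRA2A (-0.65, SE 0.09). Its adjusted p was 0.131 without control replicate 1, 0.0911 and 0.0881 without sh_TDP43 replicates 1 and 2, and 0.0834 and 0.0865 without sh_SRSF3 replicates 1 and 2. G2/M genes fell in 13 of 25 cases and rose in 2; adjusted over the list alone 14 fell and 3 rose (median -0.29, adjusted p = 0.0435; adjusted p = 0.78 with an estimated correlation). The mitotic kinase gene PLK1 fell by 1.64 (SE 0.13) and CCNB2 fell by 1.07 (SE 0.11). That call ended without control replicate 2 (adjusted p = 0.0847), without sh_TDP43 replicate 2 (adjusted p = 0.199) and with the fry test (adjusted p = 0.159).

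The other lists did not pass in sh_TDP43. Many of their members were called, but so were 6728 of all 15026 genes, so such counts alone do not set a list apart. Known TDP43 splice targets had 12 of 25 members lower and 4 higher, also adjusted over the list alone (median -0.29, adjusted p = 0.131), including the insulin receptor gene INSR at -1.43 (SE 0.13). Counts per gene sum all exons, so in either knockdown a change of splicing without a change of level would not be seen. Cell polarity genes had 9 of 18 members higher and 3 lower, and 9 and 4 adjusted over the list alone (median 0.30, adjusted p = 0.131), with NUMBL at 0.93 (SE 0.11) and LLGL1 at -0.71 (SE 0.10). Mesenchymal genes had 4 of 17 higher and 9 lower, and 5 and 9 adjusted over the list alone (median -0.27, adjusted p = 0.238); the receptor kinase gene AXL fell by 1.91 (SE 0.11) and CDH2, which encodes N-cadherin, rose by 3.07 (SE 0.23) from 1.12 ± 0.29 CPM (SD, n = 2). Epithelial genes had 5 of 18 higher and 3 lower, also adjusted over the list alone (median 0.17, adjusted p = 0.652), with CLDN4 at -2.18 (SE 0.12) and CLDN7 at -1.43 (SE 0.17). TGF-beta and YAP targets had 3 of 20 higher and 9 lower, and 4 and 9 adjusted over the list alone (median -0.18, adjusted p = 0.238). In the unfolded protein response and ATF4 list, 8 of 26 rose and 12 fell, also adjusted over the list alone (median -0.25, adjusted p = 0.238), with VEGFA at -1.73 (SE 0.10). Of p53 targets 6 of 20 rose and 6 fell, also adjusted over the list alone (median 0.05, adjusted p = 0.739), with ZMAT3 at 1.53 (SE 0.10). Cholesterol synthesis genes rose in 10 of 24 cases and fell in 6, and in 10 and 7 adjusted over the list alone (median 0.07, adjusted p = 0.479). Histone genes rose in 8 of 15 cases and fell in 1, also adjusted over the list alone (median 0.55, adjusted p = 0.208). The member that fell was H1F0, a linker histone gene expressed outside S phase. Of 28 interferon response genes, 3 rose and 7 fell, or 2 and 6 adjusted over the list alone (median -0.27, adjusted p = 0.479, and 0.013 without control replicate 1). NF-kB and cytokine genes had 2 of 22 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.926); their median was 0.18, their mean -0.01 and the direction of the test was down.

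Among 57 cytosolic ribosomal protein genes 7 fell and 0 rose, and 4 fell adjusted over the list alone (median -0.07, adjusted p = 0.432, and 0.0385 without control replicate 2). Nuclear genes of oxidative phosphorylation rose in 9 of 32 cases and fell in 2, also adjusted over the list alone (median 0.10, adjusted p = 0.197, and 0.0243 without control replicate 1). Of the 13 mitochondrially encoded genes 3 fell, also adjusted over the list alone (median -0.22, adjusted p = 0.131, and 0.0382 without control replicate 1). Long noncoding RNAs rose in 5 of 9 cases and fell in 1, also adjusted over the list alone (median 0.24, adjusted p = 0.238). Markers of other cell types gave no call: luminal breast genes (4 of 15 higher, 4 lower, also adjusted over the list alone; adjusted p = 0.76; median 0.06, mean -0.07, direction up), fibroblast genes (1 of 9 higher, 4 lower, and 3 and 4 adjusted over the list alone; adjusted p = 0.558; median -0.37, mean 0.18, direction down), haematopoietic genes (1 of 8 higher, 3 lower, also adjusted over the list alone; median -0.59, adjusted p = 0.348) and embryonic kidney packaging cell genes (1 of 3 higher, also adjusted over the list alone; median 0.23, adjusted p = 0.367).

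The comparison of sh_SRSF3 with sh_control asks the same question for SRSF3. As lists, interferon response genes, invasion proteases and integrins, Notch pathway genes and inflammatory cytokines were lower after SRSF3 knockdown at the preset correlation. Histone genes and genes of the unfolded protein response were higher as lists. None of these list calls held with an estimated correlation (camera adjusted p from 0.61 to 0.92), and not every member was called. IL11 went from 116 ± 19 to 1.27 ± 0.42 CPM (SD, n = 2), a log2 change of -6.52 (SE 0.23, adjusted p = 1.58e-10; chromosome 19, 55875757 to 55881831). PTBP1, a splicing repressor gene, fell by 2.22 (SE 0.12, adjusted p = 2.62e-09), and its neuronal paralog PTBP2 rose by 1.87 (SE 0.12, adjusted p = 8.27e-09). CDH1, which encodes E-cadherin, rose from 1.27 ± 0.35 to 15.4 ± 0.46 CPM (SD, n = 2), a log2 change of 3.59 (SE 0.23, adjusted p = 1.17e-08).

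Of the 15026 genes, 10045 passed, with 4881 higher and 5164 lower, and 4766 changed at least 2-fold (1700 higher, 3066 lower). Upper-quartile scaling shifted the median of all genes by -0.15 and gave 3959 higher and 6020 lower. The ranking here covers only genes that met the rule for named genes. Beside IL11, the strongest falls were those of SLCO4A1 (-6.18, SE 0.19), the mucin gene MUC5AC (-5.55, SE 0.33) and SPOCD1 (-5.45). They were followed by the adhesion receptor gene ADGRG1 (-5.31), NOX5 (-5.26), the transcription factor gene SPDEF (-5.13) and the inhibin subunit gene INHBB (-4.85). MUC5AC varied in the controls, at 47.3 ± 23 CPM (SD, n = 2). The strongest rises were those of ADAM32 (5.17, SE 0.26; chromosome 8, 38964509 to 39142430), the proteoglycan gene LUM (4.76, SE 0.29), the secretogranin gene SCG2 (4.42), PTPRR (4.0), the mitochondrial carrier gene UCP3 (3.90), CDH2 (3.89), UBAP1L (3.74) and PTPRQ (3.74). Adjusted p-values of these 16 genes lay between 1.31e-10 and 3.83e-07.

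Interferon response genes fell in 25 of 28 cases and none rose, with the same count adjusted over the list alone (median -1.68, adjusted p = 0.00141; adjusted p = 0.87 with an estimated correlation). IFIT3 went from 733 ± 260 to 106 ± 1.4 CPM (SD, n = 2), a log2 change of -2.79 (SE 0.21), OAS3 changed by -3.22 (SE 0.26) and the transcription factor gene IRF1 by -2.61 (SE 0.13). Invasion protease and integrin genes fell in 16 of 21 cases and rose in 1, and in 17 and 2 adjusted over the list alone (median -1.25, adjusted p = 0.00141; adjusted p = 0.61 with an estimated correlation). PLAU fell by 4.05 (SE 0.12), the integrin gene ITGB4 fell by 2.53 (SE 0.11) and MMP14 fell by 2.69 (SE 0.12); TIMP3, an inhibitor of metalloproteases, also fell, by 3.70 (SE 0.16). Notch genes fell in 14 of 18 cases and rose in 3, also adjusted over the list alone (median -1.0, adjusted p = 0.0269; adjusted p = 0.61 with an estimated correlation). The target gene HES1 fell by 2.24 (SE 0.13), NOTCH1 fell by 2.03 (SE 0.13) and LFNG fell by 3.97 (SE 0.22). Mesenchymal genes fell in 13 of 17 cases, also adjusted over the list alone (median -0.76, adjusted p = 0.0269; adjusted p = 0.61 with an estimated correlation), with TGFB1 at -1.67 (SE 0.12) and TGFB2 at -1.36 (SE 0.13). The 1 member that rose was CDH2.

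NF-kB and cytokine genes fell in 13 of 22 cases and rose in 3, also adjusted over the list alone (median -1.23, adjusted p = 0.0448; adjusted p = 0.92 with an estimated correlation), with IL6 at -3.15 (SE 0.25) and LIF at -1.47 (SE 0.10). This call ended without control replicate 2 (adjusted p = 0.225), without sh_SRSF3 replicate 1 (adjusted p = 0.0933) and with fry (adjusted p = 0.0508). Hypoxia and glycolysis genes fell in 18 of 30 cases and rose in 3, also adjusted over the list alone (median -0.43, adjusted p = 0.0297, and 0.0557 without sh_SRSF3 replicate 2; adjusted p = 0.87 with an estimated correlation). ENO2 fell by 1.78 (SE 0.09) and HK2 fell by 2.03 (SE 0.13), whereas SLC2A3 rose by 2.80 (SE 0.11). Haematopoietic markers fell in 7 of 8 cases and none rose, also adjusted over the list alone (median -1.70, adjusted p = 0.0297; adjusted p = 0.61 with an estimated correlation); the lysosomal gene CD68 was at 132 ± 20 CPM in the controls and at 37.4 ± 1.3 in sh_SRSF3 (SD, n = 2).

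Histone genes rose in 9 of 15 cases and fell in 2, and in 10 and 2 adjusted over the list alone (median 1.18, adjusted p = 0.0269; adjusted p = 0.61 with an estimated correlation). HIST1H2AC rose by 1.90 (SE 0.17) and HIST1H1C rose by 1.13 (SE 0.13), and H1F0 fell by 2.86 (SE 0.11). Histone genes are near-identical copies, and reads shared between them were not counted. In the unfolded protein response and ATF4 list 15 of 26 rose and 4 fell, and 15 and 5 adjusted over the list alone (median 0.38, adjusted p = 0.0269; adjusted p = 0.87 with an estimated correlation). DDIT3, the stress transcription factor CHOP, rose from 13.9 ± 1.2 to 105 ± 7.7 CPM (SD, n = 2), a log2 change of 2.92 (SE 0.11), the cystine transporter gene SLC7A11 rose by 2.37 (SE 0.10) and DDIT4 fell by 2.07 (SE 0.11). Nuclear oxidative phosphorylation genes rose in 12 of 32 cases and fell in 1, also adjusted over the list alone (median 0.15, adjusted p = 0.0269; adjusted p = 0.87 with an estimated correlation), with NDUFB5 at 0.69 (SE 0.09) and UQCRQ at -0.64 (SE 0.10). Without control replicate 2 the adjusted p of this list was 0.158, and its median was no larger than the shift of all genes under upper-quartile scaling. Relative to all genes of the same expression level its median was 0.01, so the typical member did not rise beyond genes of its level. This median does not speak for single members.

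**Figure D2:**
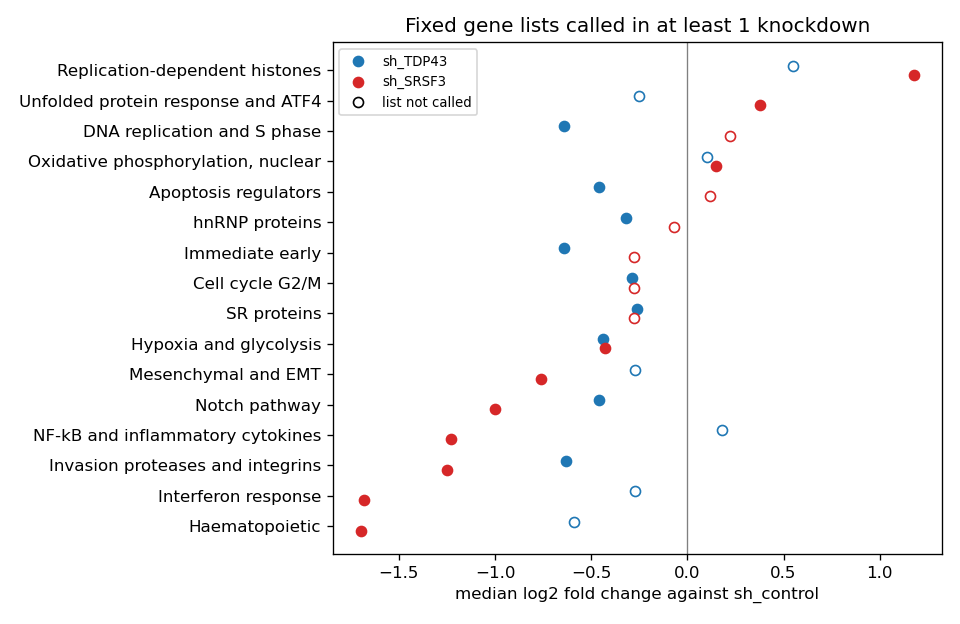
Median log2 fold change against sh_control (x axis) of each gene list (y axis) that passed camera in at least 1 knockdown, for sh_TDP43 (blue) and sh_SRSF3 (red); open points did not pass. The interferon list lies at -0.27 in sh_TDP43 and -1.68 in sh_SRSF3, and the histone list at 0.55 and 1.18; no list passed with an estimated correlation.

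The remaining lists did not pass in sh_SRSF3. SR protein genes had 6 of 13 members higher and 7 lower, also adjusted over the list alone (median -0.28, adjusted p = 0.743), with SRSF2 at -2.0 (SE 0.12) and SRSF10 at 0.93 (SE 0.09). The hnRNP genes had 10 of 30 higher and 13 lower, and 11 and 13 adjusted over the list alone (median -0.07, adjusted p = 0.743). Known TDP43 splice targets had 8 of 25 higher and 9 lower, also adjusted over the list alone (median -0.13, adjusted p = 0.743), with TNFRSF21 at -2.58 (SE 0.09). Cell polarity genes rose in 10 of 18 cases and fell in 4, and in 13 and 4 adjusted over the list alone (median 0.36, adjusted p = 0.0681); PARD6B rose by 1.31 (SE 0.13) and LLGL1 fell by 2.40 (SE 0.11). Epithelial genes rose in 7 of 18 cases and fell in 8, and in 8 and 8 adjusted over the list alone (adjusted p = 0.832; median -0.28, mean -0.01, direction up). TGF-beta and YAP targets rose in 8 of 20 and fell in 8, also adjusted over the list alone (adjusted p = 0.914; median 0.02, mean -0.30, direction down), with CTGF at -2.16 (SE 0.14). G2/M genes rose in 2 of 25 cases and fell in 14, also adjusted over the list alone (median -0.28, adjusted p = 0.125, and 0.0412 without sh_SRSF3 replicate 1), with CCNA2 at -2.52 (SE 0.15). DNA replication genes rose in 13 of 28 and fell in 8, also adjusted over the list alone (median 0.22, adjusted p = 0.304), with PCNA at 1.09 (SE 0.11).

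The p53 targets rose in 8 of 20 cases and fell in 6, also adjusted over the list alone (median 0.26, adjusted p = 0.5). Apoptosis regulators rose in 5 of 18 and fell in 4, also adjusted over the list alone (median 0.12, adjusted p = 0.743). Cholesterol synthesis genes rose in 11 of 24 and fell in 6, also adjusted over the list alone (adjusted p = 0.5; median 0.20, mean -0.08, direction up). Cytosolic ribosomal protein genes rose in 8 of 57 and fell in 6, and in 2 and 3 adjusted over the list alone (adjusted p = 0.832; median 0.00, mean -0.01, direction up). Long noncoding RNAs rose in 6 of 9 and fell in 3, also adjusted over the list alone (median 0.69, adjusted p = 0.304), with NEAT1 at 1.23 (SE 0.11). Mitochondrially encoded genes rose in 1 of 13 and fell in 6, also adjusted over the list alone (median -0.15, adjusted p = 0.5). Immediate early genes rose in 5 of 19 and fell in 10, and in 6 and 10 adjusted over the list alone (median -0.28, adjusted p = 0.304). Luminal markers (4 of 15 higher, 7 lower, also adjusted over the list alone; median -0.18, adjusted p = 0.743), fibroblast markers (2 of 9 higher, 4 lower, also adjusted over the list alone; median -0.70, adjusted p = 0.5) and packaging cell markers (1 of 3 higher, also adjusted over the list alone; median 1.17, adjusted p = 0.392) did not pass either.

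The libraries of the knockdowns were also compared with each other, which tests the difference between them. As lists, replication genes and stress genes of the ATF4 pathway were lower in sh_TDP43 than in sh_SRSF3, and interferon and cytokine genes were higher. None of these list calls held with an estimated correlation (camera adjusted p = 0.94 each). The interferon and cytokine calls also ended with fry. The glucose transporter gene SLC2A3 was lower in sh_TDP43. SLC2A3 differed by -4.50 (SE 0.12), SCG2 by -5.42 (SE 0.21), SMPD3 by -4.34 (SE 0.26) and MYBL2 by -4.06 (SE 0.17). Only genes that met the rule for named genes were ranked. Among them the keratin gene KRT17 (5.63, SE 0.58), MUC5AC (4.92, SE 0.33), DBH (4.77, SE 0.32) and CCDC190 (4.59, SE 0.29) were furthest higher. Of 15026 genes 9842 passed, 5041 higher and 4801 lower in sh_TDP43, and 4595 differed at least 2-fold (3006 higher, 1589 lower). Upper-quartile scaling shifted the median of all genes by 0.25 and gave 6451 higher and 3378 lower. TARDBP differed by -1.67 (SE 0.13) and SRSF3 by 1.55 (SE 0.10). PARD3 differed by -0.29 (SE 0.09, adjusted p = 0.0141), a call that ended under upper-quartile scaling (-0.05, adjusted p = 0.688), without sh_TDP43 replicate 1 (adjusted p = 0.106) and without sh_SRSF3 replicate 2 (adjusted p = 0.201). NUMB differed by 0.18 (SE 0.10, adjusted p = 0.144, and 0.00277 under upper-quartile scaling).

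DNA replication genes were lower in sh_TDP43 than in sh_SRSF3 in 23 of 28 cases and higher in 1, also adjusted over the list alone (median -1.01, adjusted p = 5.35e-05; adjusted p = 0.94 with an estimated correlation), with PCNA at -2.06 (SE 0.12) and MCM6 at -1.64 (SE 0.12). Unfolded protein response and ATF4 genes were lower in 18 of 26 cases and higher in 2, also adjusted over the list alone (median -0.77, adjusted p = 0.00102; adjusted p = 0.94 with an estimated correlation), with SLC7A11 at -3.28 (SE 0.10) and ASNS at -1.90 (SE 0.11). Apoptosis regulators were lower in 9 of 18 cases and higher in 0, also adjusted over the list alone (median -0.46, adjusted p = 0.0148; adjusted p = 0.94 with an estimated correlation), with BCL2L1 at -1.68 (SE 0.10). Interferon genes were higher in 24 of 28 cases and lower in 0, also adjusted over the list alone (median 1.51, adjusted p = 0.00127; adjusted p = 0.94 with an estimated correlation and 0.0942 with fry), with IFIT3 at 3.0 (SE 0.22) and ISG15 at 1.60 (SE 0.15). Cytokine and NF-kB genes were higher in 16 of 22 cases and lower in 2, also adjusted over the list alone (median 1.36, adjusted p = 0.0295; adjusted p = 0.94 with an estimated correlation). The last call ended without sh_TDP43 replicate 2 (adjusted p = 0.101), without sh_SRSF3 replicate 1 (adjusted p = 0.0815) and with fry (adjusted p = 0.0827). The other 23 lists did not pass, with adjusted p-values from 0.182 for the haematopoietic list (median 0.90) to 0.914 for the immediate early and long noncoding RNA lists. Median and direction of the test differed in sign for the SR protein (0.04, down), cell polarity (0.04, down) and TGF-beta lists (0.02, down), and mean and direction for the epithelial list (0.05, down). Median and mean differed in sign for the TDP43 splice target (-0.31 and 0.02), p53 (-0.36 and 0.02), cholesterol (-0.10 and 0.09) and immediate early lists (-0.22 and 0.22).

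Many genes changed in both knockdowns. SLCO4A1, IL11, NOX5, PLAU, JAG1, LFNG and PTBP1 fell in both, and PTPRQ, PTPRR, CDH2, NEAT1 and ZMAT3 rose in both. Over all genes, 1689 were higher in both and 1980 lower in both, where independent lists would share 1009 and 1245. Opposite changes were fewer than independent lists would give, at 560 genes higher in sh_TDP43 and lower in sh_SRSF3 (independent 1067) and 797 the other way (independent 1177). Of 5026 genes called in both, 3669 (73%) moved the same way. Both comparisons use the same control libraries. In 40 simulations with every library drawn around the control level, the groups shared at most 1 called gene. With nothing changed almost no gene is called, so this count does not measure what shared controls add to real calls. Across genes, which are not independent replicates, the log2 changes correlated at 0.403, below the 0.499 of simulated unchanged groups, and their covariance was 0.524 against at most 0.0408 in the simulations. With 2 control libraries, no split leaves at least 2 of them to each knockdown, so part of the excess over independent lists may come from the shared controls.

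RNA recovered with Flag-TDP43 was compared with its input to list the RNAs recovered with the protein. The labels name no control pulldown for either RIP, so binding cannot be told apart from background recovery. There is 1 library on each side, so the values describe these libraries and carry no error. Among the 10 highest ratios were 3 small Cajal body RNAs, a class that guides the modification of spliceosomal RNAs: SCARNA2 was at 8110 FPKM in the RIP and 428 in the input (log2 ratio 4.24), SCARNA7 at 1540 and 56.3 (4.75) and SCARNA9 at 102 and 1.08 (5.63). RNU11, the U11 RNA of the minor spliceosome, was at 87.4 FPKM in the RIP and is listed at 0 in the input. TARDBP itself was at 80.4 FPKM in the RIP and 14.2 in the input (2.42), while the input of the Flag-SRSF3 cells had 1.76.

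Of 10647 genes at 1 FPKM or more in either library, 1690 (15.9%) were at least 2-fold higher in the TDP43 RIP and 1391 (13.1%) at least 2-fold lower. The second deposited table had 1578 higher, of which 1099 were among the 1690, and the ratios of the tables correlated at 0.83 across genes. DYRK1A (4.69), MFN2 (4.64), GTPBP1 (4.29) and ANXA3 (5.2) were among the highest ratios. Entries for the signal recognition particle RNA, RN7SL3 (4.80) and one of those named RN7SL1 (4.72), were too. In the second deposited table the log2 ratios were lower, at 2.64 for DYRK1A, 1.64 for MFN2, 1.97 for GTPBP1 and 0.28 for ANXA3. RN7SL3 had a ratio of -8.27 there and that RN7SL1 entry of -4.14. The lowest ratios were those of RN7SL4P (-10.99), RPPH1, the RNA of RNase P (-8.41), the other entry named RN7SL1 (-8.14), RN7SL5P (-7.11) and RNU2-2P (-6.81). The RN7SL and U2 RNAs come from near-identical copies and their values are uncertain. Both RN7SL1 entries cover the same locus, so their ratios of 4.72 and -8.14 are not those of separate RNAs. SRSF3 had a ratio of 1.48 (0.43 in the second table), PARD3 of 0.43 (0.28), NUMB of 0.69 (-0.75), MALAT1 of 0.74 (1.01) and GAPDH of -2.77 (-2.97). NEAT1 was below 1 FPKM in both libraries and had a ratio of 1.58 in the second table. Mitochondrially encoded RNAs had a median log2 ratio of -1.80 (percentile 0 of 10000 random lists matched on expression), histone genes of -1.72 (percentile 0.02), luminal markers of -0.94 (0.37), ribosomal protein genes of -0.35 (0.48) and invasion genes of -0.50 (1.41). The other lists tested lay within the central 95% of random lists; the fibroblast, haematopoietic and packaging cell lists had too few genes kept to test.

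The Flag-SRSF3 RIP gave other RNAs. Immediate early genes were recovered with SRSF3, at a median log2 ratio of 1.45 (percentile 100), as were mitochondrially encoded RNAs (1.85, percentile 99.99) and histone genes (1.24, percentile 99.58). Nuclear oxidative phosphorylation genes were at -0.62 (percentile 0), long noncoding RNAs at -0.47 (0.13), SR protein genes at -0.38 (1.38) and apoptosis regulators at -0.29 (2.47). For neither RIP were list medians taken in the second table. SRSF3 itself was at 91.3 FPKM in the RIP and 54.9 in the input (0.72).

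Of 10693 genes kept, 1574 (14.7%) were at least 2-fold higher in the SRSF3 RIP and 729 (6.8%) lower. The median log2 ratio of all genes kept was 0.18, and after centring on it 1102 were at least 2-fold higher. The second table had 1191 higher, of which 798 were among the 1574, and the tables correlated at 0.73 across genes. The highest ratios were those of HIST2H3A (6.28), VIM-AS1 (6.16), RN7SKP71 (6.14), BLOC1S5-TXNDC5 (5.16), EHD1 (5.13), ARCN1 (5.07), HMGA1P3 (4.77), RPS24 (4.52) and LARP1 (4.49), and SPANXC was at 31 FPKM with an input listed at 0. Several were far lower in the second table: HIST2H3A 0.87, EHD1 0.80, RPS24 0.82, LARP1 0.41, ARCN1 -0.09 and RN7SKP71 -1.69. VIM-AS1 overlaps VIM on the other strand, and whether reads were assigned by strand is not given in the sources used here. The lowest were RN7SL1 (-8.64), RN7SL4P (-8.22), RPPH1 (-7.94), RN7SL5P (-7.70) and RPL13A (-6.03, and -0.42 in the second table). PARD3 was at 0.27 (-0.09 in the second table), NUMB at 0.25 (-0.2), TARDBP at -0.16 (-1.45) and GAPDH at 1.53 (1.62).

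The RNAs at least 2-fold higher in each RIP were mostly not those of the other. GAPDH was lower than input with TDP43 and higher with SRSF3, as were mitochondrially encoded and histone RNAs. Genes at least 2-fold higher in both RIPs numbered 139 of 11530, where independent lists would share 231. This count was 273 with a pseudocount of 0.1, 87 at 5 FPKM or more, 12 at 4-fold, 74 in the second table and 37 for genes enriched in both tables. The 2 lists also changed size, to 2267 and 2321 genes at a pseudocount of 0.1 and to 395 and 206 at 4-fold. Numbers for independent lists were not computed at these settings, so whether the shortfall holds there is not known. The log2 ratios correlated at -0.11 across genes, which are not independent replicates. The inputs correlated at 0.93.

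RNAs recovered with each protein were then followed in its knockdown. Of 1443 genes higher in the TDP43 RIP and tested in sh_TDP43, 289 (20%) rose and 473 (32.8%) fell, against 19.7% and 31.4% of other genes matched on expression, and both medians were -0.08. Camera compared the recovered genes with all tested genes, not with matched ones. It gave them a lower position with adjusted p = 0.0445, and p = 0.25 with an estimated correlation. That call ended with a pseudocount of 0.1, at 4-fold enrichment and with the second table. The p-value of camera became 0.0595 without control replicate 1 and 0.102 without sh_TDP43 replicate 2. Of 1341 genes higher in the SRSF3 RIP and tested in sh_SRSF3, 379 (28.3%) rose and 612 (45.6%) fell, against 39.1% and 33.6% of matched genes. Their median log2 change was -0.21 against 0.07 for the others (adjusted p = 0.0445; p = 0.075 with an estimated correlation), and at 4-fold enrichment the p was 0.498.

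The log2 fold changes in the authors' deposited table equal log2 of RIP over input FPKM: 0 of 16997 finite values for TDP43 and 0 of 17062 for SRSF3 differed by over 0.01. Across the genes kept they correlated with the ratios given here, which carry a pseudocount, at 0.91 for TDP43 and 0.9 for SRSF3.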

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

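All tests of explanations in this part were chosen after the results were seen; the comparison of the knockdowns with each other was planned. The 5 lists that differed between the knockdowns by a direct test are given here.

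DNA replication genes were lower in sh_TDP43 than in sh_SRSF3 (adjusted p = 5.35e-05, median -1.01), with 23 of 28 lower. Unfolded protein response and ATF4 genes were lower in sh_TDP43 (adjusted p = 0.00102, median -0.77). Apoptosis regulators were lower in sh_TDP43 (adjusted p = 0.0148, median -0.46). NF-kB and cytokine genes were higher in sh_TDP43 (adjusted p = 0.0295, median 1.36), with adjusted p = 0.101 without sh_TDP43 replicate 2 and 0.0815 without sh_SRSF3 replicate 1. None of these held with an estimated correlation (adjusted p = 0.94 each).

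Interferon genes fell by a median of 1.68 on the log2 scale in sh_SRSF3 and differed between the knockdowns (adjusted p = 0.00127; adjusted p = 0.94 with an estimated correlation and 0.0942 with fry). If the control libraries alone had raised interferon genes, both knockdowns would lie equally far below them. The median between sh_TDP43 and sh_SRSF3 was 1.51, and 24 of 28 members were called higher in sh_TDP43. This difference does not use the controls. The same comparison singled the list out, so its outcome was known and it gives no separate support. Members also moved together (estimated correlation 0.921), so 24 of 28 does not stand for 24 separate measurements. IFIT3 varied widely between the control libraries (SD given above), so the size of the fall against the controls may rest partly on a single control library. A trend of fold change with expression level is argued against, since the list lay at -1.85 relative to genes of the same expression level. A lower interferon signal after SRSF3 knockdown may be biological, as a hypothesis, yet the sequence of the single hairpin and the delivery of the virus stay open and untested. A second hairpin or a rescue of SRSF3 would test the hypothesis.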

How the results depend on the processing

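Among main values 198 stayed on the same side or within 1.5 times, 17 moved, 8 lost their call and 0 reversed. For single genes and lists these were 5790, 152, 71 and 4, and 47 gained a call. Named RIP ratios counted as moved at almost any difference, large or small, and are among the 152. Dropping the filter could not change the RIP counts, since a 2-fold ratio with a pseudocount of 1 needs at least 1 FPKM. Those settings are among the 198. The combined knockdown comparisons and the interaction were not run under any alternative. Alternatives with the second deposited table were chosen after seeing the data. The cause of a change was not tested, except where fewer libraries or a stricter threshold bring it.

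Leaving out each replicate in turn gave 4486 to 6576 calls in sh_TDP43 (1487 to 1930 at least 2-fold), 8749 to 9796 in sh_SRSF3 (4413 to 4722) and 8268 to 10165 between the knockdowns (4073 to 4649). The count for sh_TDP43 was 1.5 times below the full count without sh_TDP43 replicate 2. TARDBP ranged from -2.36 to -1.93 and SRSF3 from -2.87 to -2.68. Genes higher in both numbered 1154 to 1481 and lower in both 1478 to 1906, and lists passing 7 to 11, 8 to 10 and 4 to 5. With the replicate block there were 7672, 10565 and 10413 calls. Same-numbered libraries deviated together at 0.128, 0.09 and 0.094, so the numbers are not taken as pairing.

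At 2-fold or more, 361 genes were higher in both knockdowns and 544 lower in both. Passing lists were 0, 0 and 0 with an estimated correlation and 18, 17 and 10 with fry. At 4-fold, 395 genes were enriched with TDP43 and 206 with SRSF3. Genes enriched in both RIPs numbered 273 at a pseudocount of 0.1, 87 at 5 FPKM or more, 12 at 4-fold, 74 in the second table and 37 in both tables. Numbers for independent lists were not computed at these settings. Among named ratios of at least 2-fold either way, those with the other sign in the second table were RN7SL3 (-8.27), RN7SL1 (-4.14), RN7SKP71 (-1.69) and ARCN1 (-0.09). The TDP43-recovered genes in sh_TDP43 had p = 0.107 at a pseudocount of 0.1, 0.0518 at 4-fold, 0.0858 in the second table and 0.245 with an estimated correlation, and 0.0152 to 0.102 without each replicate. The SRSF3-recovered genes in sh_SRSF3 had p = 0.498 at 4-fold and 0.0748 with an estimated correlation, and 0.0177 to 0.0424 without each replicate. Deposited RIP fold changes correlated with the pseudocount ratios at 0.74 and 0.72 over all genes. Depth limits genes below a few CPM, and in the RIPs 1 library per side gives no error.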

Other observations

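The gene families in this part were chosen by symbol after values were seen, 22 families in all, and all tests of explanations here were chosen after the results were seen. In sh_TDP43, pregnancy-specific glycoprotein genes rose in 7 of 9 cases (median log2 change 1.98, camera adjusted p = 0.00255; adjusted p = 0.61 with an estimated correlation), with PSG5 at 3.08 (SE 0.31) and PSG4 at 1.98 (SE 0.21). Their levels are low (PSG4 at 2.88 CPM in the controls) and they share reads with each other, so single members are uncertain. Tubulin genes fell in 12 of 20 cases and none rose (median -0.47, adjusted p = 0.0105; adjusted p = 0.63 with an estimated correlation). TUBB6 fell by 2.64 (SE 0.11), TUBB2A fell by 1.11 (SE 0.13) and TUBB fell by 0.78 (SE 0.10).

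In sh_SRSF3, mitochondrial ribosomal protein genes rose in 35 of 77 cases and fell in 7 (median 0.24, adjusted p = 0.0155; adjusted p = 0.68 with an estimated correlation), and complex I genes rose in 21 of 45 and fell in 2 (median 0.26, adjusted p = 0.00958; adjusted p = 0.67 with an estimated correlation). Aminoacyl-tRNA synthetase genes rose in 12 of 18 and fell in 4 (median 0.59, adjusted p = 0.0326; adjusted p = 0.67 with an estimated correlation). Heat shock and DNAJ genes rose in 36 of 68 and fell in 16 (median 0.46, adjusted p = 0.0354; adjusted p = 0.57 with an estimated correlation). Zinc finger genes rose in 203 of 457 and fell in 95 (median 0.33, adjusted p = 0.00823; adjusted p = 0.57 with an estimated correlation). All histone-named genes rose in 14 of 28 cases and fell in 1 (median 1.16, adjusted p = 0.00175; adjusted p = 0.57 with an estimated correlation). Solute carrier genes fell in 123 of 255 and rose in 68 (median -0.48, adjusted p = 0.0424; adjusted p = 0.46 with an estimated correlation), protocadherin genes fell in 8 of 29 and rose in 1 (median -0.67, adjusted p = 0.0424; adjusted p = 0.57 with an estimated correlation), and tubulin genes fell in 13 of 20 and rose in 1 (median -0.46, adjusted p = 0.0424; adjusted p = 0.57 with an estimated correlation).

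Log2 changes moved with expression level in opposite ways. With genes in 10 bins by level, the median of the lowest bin was 0.40 in sh_TDP43 and -0.44 in sh_SRSF3, and that of the highest bin -0.04 and 0.19. Across genes Spearman's rho was -0.15 in sh_TDP43 and 0.21 in sh_SRSF3. Relative to all genes of the same level, the medians of families in sh_SRSF3 were 0.2 for mitochondrial ribosomal proteins, 0.19 for complex I, 0.37 for aminoacyl-tRNA synthetases, 0.39 for heat shock and DNAJ genes, 0.58 for zinc fingers and 1.57 for histones. They were -0.32 for solute carriers, -0.19 for protocadherins and -0.57 for tubulins.

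The knockdowns moved many genes the same way. Replicate noise in the shared control libraries as the whole cause is argued against by the covariance of the log2 changes. It was 0.524, against at most 0.0408 in simulations of unchanged groups. These simulations hold replicate noise alone, so a shift common to both control libraries cannot be excluded by them. Loss of SRSF3 RNA in the sh_TDP43 libraries may account for part of it. Of genes called in both, 73% moved the same way, against 50.1% for independent calls, but a response common to both losses would give the same, so these cannot be told apart without libraries in which SRSF3 is kept while TDP43 is lost. A hairpin effect common to both stays open and untested.

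SRSF3 was lower in sh_TDP43 as well. Mixing of sh_SRSF3 cells or RNA into the sh_TDP43 libraries would have to make up 67.1% of them, and the 1446 genes at least 4-fold lower in sh_SRSF3 would then lie at a median of -1.23 or below in sh_TDP43. Their median there was -0.49 (quartiles -1.07 and 0.07), and 93 of them were called higher than in the controls. This argues against mixing at that share as the whole cause, if the other cells had these genes at the control level. A smaller share of mixing was not tested. A lower SRSF3 level after TDP43 loss may be biological, as a hypothesis, and an off-target effect of the hairpin stays open and untested; a second hairpin or a rescue of TDP43 would test it.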
